A study of Homo sapiens with 10 samples.

How the data were processed

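RNA from human endometrial stromal cells was hybridised to 10 Affymetrix oligonucleotide arrays, 2 for each of 5 groups. The groups were vehicle with a non-target siRNA, and the differentiation mixture cAME with a non-target siRNA, with an siRNA against KLF9, with an siRNA against PGR, or with both targeting siRNAs. Per the labels' protocols, cAME holds 8-bromo-cAMP, 17β-estradiol and medroxyprogesterone acetate, RNA was extracted with an RNeasy Plus kit, and biotin-labelled amplified RNA was hybridised. The labels do not say whether the cells are a line or a primary culture. They number the arrays of each group as pool 1 and pool 2 and do not explain the word, so nothing says that the replicates came from separate cultures, and the p-values measure only the spread between these arrays, which may be technical.

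The deposited table holds 1 log2 value per probe set and array, for 54675 probe sets. GCOS and GCRMA appear in the submitters' processing notes, with no version and no role stated. The log base is not stated, and it was taken as 2 because GCRMA returns log2 values. Each probe set had been centred on its median over the 10 arrays, to within 5e-07, before deposit. Who did so is not stated. The absolute level of every probe set was thereby lost, so that no filter on dim probe sets could be set, no background level could be printed, and a value has a meaning only as a difference between arrays. A fold change here assumes log2 values. For arrays, their number limits the precision.

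Of the probe sets, 62 hybridisation and quality controls and 95 for XIST and Y-linked genes were left out, and 54518 were tested. Gene names came from the platform annotation supplied with the series, whose symbols were checked against the RefSeq gene table of assembly GRCh38.p14 through their Entrez numbers. The check changed 0 symbols. Exactly 1 gene was listed for 41032 of the tested probe sets, several for 1765, and none for 11721. The probe sets with 1 gene stood for 19740 genes, of which 10511 had more than 1 probe set. The rule written first, to keep the probe set with the highest mean, cannot be applied to centred values, and the probe set with the largest standard deviation over the 10 arrays was kept instead, a choice made without the group labels but after the values had been seen. Among genes changed at least 2-fold, the gene's other varying probe sets pointed the same way in 91.4% of cases for cAME, 92.3% for siKLF9, 85.4% for siPGR and 88.9% for both siRNAs. A range under 0.2 over the 10 arrays was seen for 7467 genes, called flat here; they stayed in the test, and the other 12273 are called varying.

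A linear model with 1 mean per group was fitted to the deposited values of all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with no replicate block. It left 5 residual degrees of freedom. The comparisons were cAME against vehicle, both with the non-target siRNA. Within cAME, each siRNA and the pair were compared with the non-target siRNA, the pair with each single siRNA, and the single siRNAs with each other. The interaction was the joint change minus the sum of the single changes. All tests were two-sided. P-values were adjusted by Benjamini and Hochberg over the 19740 genes of each comparison, and a gene was called changed at an adjusted p below 0.05. Values are log2 differences of group means with the standard error of the model, and n is 2 arrays per group throughout.

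In all, 28 gene lists were fixed. For each list, the calls over all genes and the calls adjusted over the list alone were counted, and camera was run with a preset correlation of 0.01 on lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, limma's rotation test of a list by itself, were run as alternatives. The design, the lists, the alternatives and the rule for named genes were written before the data were examined, except where stated. That rule takes KLF9, PGR, PRL and IGFBP1 everywhere. It adds the 10 largest rises and 10 largest falls among the called genes of cAME, siKLF9, siPGR and the pair, and up to 4 members per list with the smallest p. Genes called with both single siRNAs and the pair were taken as the 10 per direction with the largest mean change, and the interaction and the pair against each single siRNA as the 5 per direction with the smallest p. The text names the first of these.

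The comparisons that share the non-target arrays share their chance values. For these, 100 draws of unchanged groups with the spread of the real arrays gave the covariance and correlation that shared arrays produce alone. The steps were tested on simulated normal values, drawn for each gene independently with the spread that the model gave it. With 200 of 19740 genes changed in the siKLF9 comparison, 34.7% were recovered at a log2 change of 0.5, 70.1% at 1 and 93% at 2, and 7% of the called genes were false, over 20 draws. A list shifted by 0.3 in the siPGR comparison was called in 20 of 20 draws, with 0 other lists called. The simulated genes did not vary together, whereas the estimated correlation within the interferon list was 0.187 on the real arrays. The check therefore does not show how often a list of correlated genes is called falsely.

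The alternatives were every probe set tested on its own, the mean of a gene's probe sets, trend and robust variance estimates, quantile normalization, equal array medians, the replicate number as a block, a fit on the compared groups alone, other thresholds, and leaving out each array. After an array was left out, the lone array of its group was taken to vary like the other groups. Leaving out the flat genes was added after the data were seen, as were the use of 1 non-target array per comparison for the covariances and a fit of the pair against siPGR without the non-target cAME arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.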

Results

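Endometrial stromal cells differentiate into decidual cells under progestin and cyclic AMP, and the series asked which genes and pathways the progesterone receptor PGR and the transcription factor KLF9 regulate together in that state. Transcript levels were measured on 10 arrays, 2 in each of 5 groups. One group received vehicle, and the others received cAME, a mixture of a cyclic AMP analogue, estradiol and a synthetic progestin. The vehicle group and 1 cAME group carried a non-target siRNA, and the other cAME groups carried siKLF9, siPGR or both. The deposited values carry no depth or level per array, because each probe set was centred on its median. Over the 12273 varying genes, the standard deviation of the difference between replicates ran from 0.211 in the cAME non-target group to 0.291 in the vehicle group. The first principal component, with 69% of the variance, placed the vehicle arrays at -75.7 and -74.3 and the 8 cAME arrays between 16.9 and 20.9. The second, with 15%, placed the 4 arrays with siPGR between 12.7 and 25.1 and the 4 cAME arrays without it between -21.4 and -17.1. The third, with 4.52%, placed the 4 arrays with siKLF9 between -11.2 and -9.97 and the 4 cAME arrays without it between 7.85 and 12.7.

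The siRNAs lowered their targets in the arrays that carried them. The main KLF9 probe set read 1.73 and 1.91 on the cAME non-target arrays and 1.38 and 1.77 with siPGR. It read -0.07 and 0.07 with siKLF9 and -0.73 and -1.16 with both siRNAs, against -0.67 and -0.45 in the vehicle arrays. The main PGR probe set read 0.48 and 0.10 with the non-target siRNA and 0.67 and 0.58 with siKLF9, but -2.32 and -2.02 with siPGR and -2.52 and -2.02 with both. In the vehicle arrays it read 0.01 and -0.01. KLF9 transcript was left at 28.4% of the cAME non-target level with siKLF9, 84.6% with siPGR and 14.8% with both, and PGR transcript at 126%, 18.1% and 16.9%. KLF9 changed by -1.82 ± 0.19 with siKLF9 (adjusted p = 0.028) and by -2.76 ± 0.19 with both (adjusted p = 0.0011). PGR changed by -2.46 ± 0.21 with siPGR (adjusted p = 0.0042) and by -2.56 ± 0.21 with both (adjusted p = 0.0016). A second KLF9 probe set gave -1.90 ± 0.09 with siKLF9 (adjusted p = 0.00668 over all tested probe sets) and -2.50 ± 0.09 with both (adjusted p = 0.00027). The 3 others gave -0.193, -0.003 and -0.151 with siKLF9 and -0.196, -0.003 and -0.198 with both. A second PGR probe set gave -2.57 with siPGR and -2.41 with both. The cross effects did not pass the test, at 0.33 ± 0.21 for PGR with siKLF9 (adjusted p = 0.8) and -0.24 ± 0.19 for KLF9 with siPGR (adjusted p = 0.8). The KLF9 call with siKLF9 was lost by leaving out vehicle array 1 or 2 (adjusted p = 0.0541), non-target array 1 (0.0581) or 2 (0.0828), or siKLF9 array 1 (0.0653) or 2 (0.0603). It was lost too in the fit on the compared groups alone (adjusted p = 0.116).

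**Figure D1:**
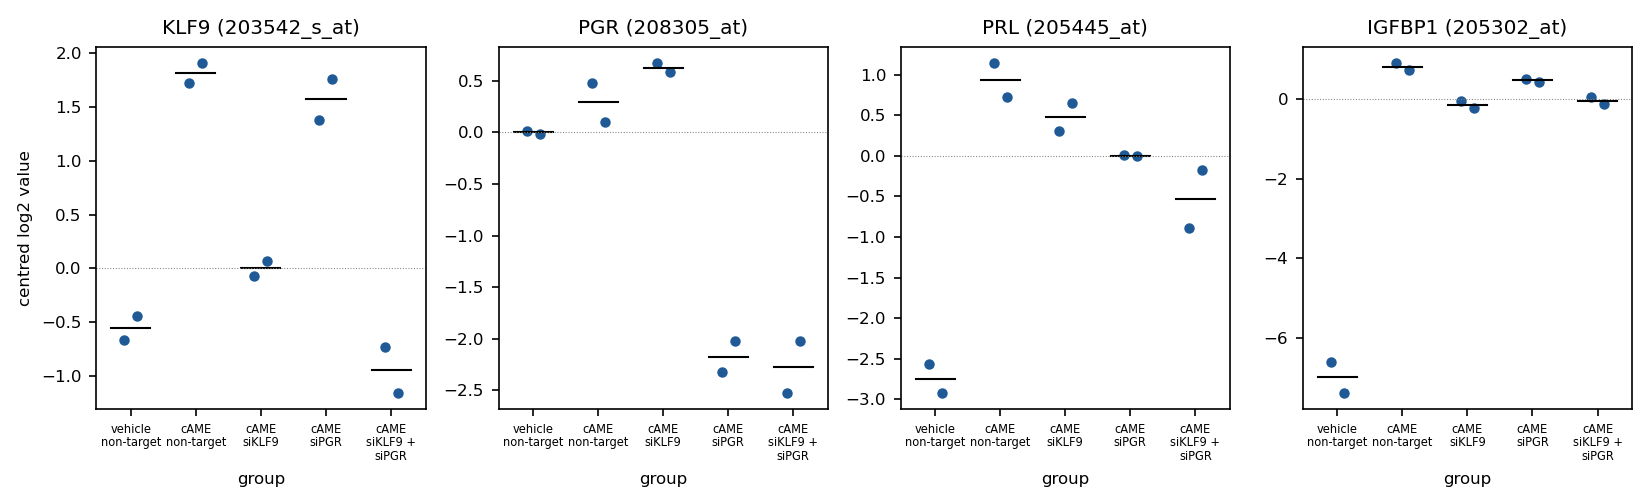
Centred log2 values of KLF9, PGR, PRL and IGFBP1 (vertical axes, 1 probe set each) on the 2 arrays of each of the 5 groups (horizontal axes); points are arrays, bars are group means and the dotted line is 0. KLF9 stood at or below 0.07 on all 4 arrays with siKLF9, PGR at or below -2.02 on all 4 arrays with siPGR, and the vehicle arrays were the lowest for PRL and IGFBP1.

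Differentiation with cAME raised the classical decidual transcripts and lowered those of cell division. PRL, the prolactin gene, rose by 3.67 ± 0.28 (adjusted p = 0.00025), and IGFBP1, an IGF-binding protein secreted by decidual cells, by 7.80 ± 0.24 (adjusted p = 1e-05). The largest rises were those of CGA, the common subunit of the glycoprotein hormones (9.00 ± 0.05), the growth factor IGF1 (8.71 ± 0.10), the orphan nuclear receptor RORB (8.55 ± 0.15), somatostatin SST (8.42 ± 0.22) and the cannabinoid receptor CNR1 (7.91 ± 0.13). KLF9 itself rose by 2.37 ± 0.19 (adjusted p = 0.00033), whereas PGR showed 0.29 ± 0.21 (adjusted p = 0.29). Its second probe set gave 0.62, and with the mean of its probe sets PGR rose by 0.45 (adjusted p = 0.0387). Among the largest falls were the keratin-associated KRTAP1-5 (-7.14 ± 0.12), the chemokine CXCL3 (-5.84), the imprinted gene MEST (-5.65) and the receptor tyrosine kinase KIT (-5.33). RRM2, a subunit of ribonucleotide reductase, stood at -5.62 ± 0.39 and ANLN, a protein of the cytokinetic ring, at -5.37 ± 0.16. CDC20 and CCNB2, which drive mitosis, stood at -5.14 ± 0.20 and -4.99 ± 0.24. In all, 5611 of 19740 genes were called, 2628 higher and 2983 lower, of which 1675 changed at least 2-fold and 735 by less than 0.2. The larger direction turned with trend and robust variance estimates (5165 higher and 3224 lower) and with every probe set on its own (7491 and 5455). It held at 2-fold (634 and 1041) and without the flat genes (2111 and 3193). Flat genes made up 576 of the 5611 calls. The median of flat probe sets was -0.0275 and -0.0173 on the vehicle arrays, and 0.0047 and 0.0025 on the non-target arrays. Quantile normalization called 2532 genes. It forces 1 distribution on all arrays, which suits centred values poorly. The standard deviation over varying probe sets was 0.68 and 0.675 on the vehicle arrays, but 0.222 and 0.223 on the non-target arrays.

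Among the gene lists, the decidual markers had 15 of 22 members higher and 2 lower over all genes, and 17 and 2 adjusted over the list alone (camera adjusted p = 9.79e-07), with FOXO1, a decidual transcription factor, at 4.04 and the WNT inhibitor DKK1 at 2.29. The steroid-responsive genes had 14 of 18 higher and 1 lower, or 15 and 1 adjusted over the list alone (1.19e-08). HSD11B1, which makes active glucocorticoid, rose by 5.36, the receptor chaperone FKBP5 by 5.16 and the amine oxidase MAOA by 5.03. Mitosis genes had 0 higher (unadjusted 0) and 32 of 35 lower, the same counts adjusted over the list alone (8.36e-27), with the survivin gene BIRC5 at -4.07 and NUSAP1 at -3.90. DNA replication genes had 0 higher (unadjusted 1) and 24 of 31 lower, or 1 and 26 adjusted over the list alone (4.66e-17), with the helicase subunit MCM4 at -1.72 and GINS2 at -3.90. Of the histone and chromatin genes, 2 of 26 were higher and 11 lower, or 3 and 11 adjusted over the list alone (0.000107), with HMGA2 at -4.11 and HDAC9 at -4.51. These 5 calls held with an estimated correlation.

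Another 6 lists shifted with the preset correlation, and their calls were lost with the estimated one. Interferon-response genes had 2 of 42 higher and 29 lower, or 3 and 33 adjusted over the list alone (camera adjusted p = 6.53e-13; adjusted p = 0.0913 with an estimated correlation), with the transcription factor IRF1 at -2.36 and IFIT3 at -1.40. The contractile genes had 1 of 25 higher and 16 lower, or 2 and 16 adjusted over the list alone (2.19e-07; adjusted p = 0.0741 with an estimated correlation), with the myosin kinase MYLK at -3.44 and TAGLN at -2.03. The ACTB control probe sets for the 5′ and 3′ ends were both lower in the cAME non-target arrays than in vehicle. Their centred 5′ minus 3′ difference was 0.567 in vehicle and 0.137 in the cAME non-target arrays. The p53 and apoptosis genes had 2 of 26 higher and 15 lower, or 3 and 16 adjusted over the list alone (8.9e-07; adjusted p = 0.0741 with an estimated correlation), with PMAIP1 at -2.25 and DDB2 at -1.97. Of the cAMP and CREB targets, 12 of 22 were higher and 3 lower, or 13 and 3 adjusted over the list alone (0.00044; adjusted p = 0.0913 with an estimated correlation), with the kinase SIK1 at 3.25 and RGS2 at 3.0. The IGF axis had 9 of 17 higher and 3 lower, or 9 and 4 adjusted over the list alone (0.0373; adjusted p = 0.428 with an estimated correlation), with the IGFBP protease PAPPA at 1.40 and the secreted STC2 at -3.33. Collagens and matrix genes had 8 of 45 higher and 16 lower, or 9 and 17 adjusted over the list alone (0.0117; adjusted p = 0.499 with an estimated correlation), with POSTN at -3.51, FN1 at -2.71 and the proteoglycan VCAN at 3.66. Leaving out siKLF9 array 1 or 2 ended the call of the IGF axis (adjusted p = 0.0694), and the other 10 list calls held without any 1 array.

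No shift was called by camera for the other 17 lists. Counts of higher and lower members, then adjusted over the list alone, were 8 and 7 of 41 (8 and 8) for the WNT pathway, 11 and 9 of 43 (12 and 12) for BMP and TGFB, and 2 and 2 of 21 (1 and 1) for Notch. Matrix proteases had 12 and 7 of 39 (14 and 8 adjusted over the list alone), and cytokines 9 and 13 of 41 (10 and 13), among them CXCL2 at -4.89, CXCL1 at -3.15 and CCL8 at 5.31. The unfolded protein response had 8 and 11 of 27 (9 and 11 adjusted over the list alone), sterol synthesis 4 and 4 of 19 (4 and 5), and retinoid and steroid metabolism 11 and 5 of 31 (13 and 5), with the retinal dehydrogenase ALDH1A3 at 4.78. Oxidative defence had 13 and 6 of 27 (14 and 6 adjusted over the list alone), and hypoxia and glycolysis 6 and 9 of 30 (10 and 12), with PDK4, a brake on pyruvate oxidation, at 5.70. The KLF and SP family had 5 and 7 of 22 (5 and 7 adjusted over the list alone) and the nuclear receptors 6 and 6 of 27 (8 and 10). Of the cell type markers, the epithelial list had 0 higher (unadjusted 5) and 3 lower of 16 (0 and 3 adjusted over the list alone), the lower ones being the keratins KRT19 at -4.12, KRT18 at -3.13 and KRT8 at -0.69. The pericyte list had 3 and 4 of 13 (3 and 4 adjusted over the list alone), with KCNJ8 at 2.88, and the mesenchymal list 4 and 7 of 16 (5 and 8). The endothelial list had 1 higher and 0 lower of 13 (0 and 0 adjusted over the list alone, 3 and 0 unadjusted), the 1 call being ERG at 0.19. That call was lost without vehicle array 1 or non-target array 1 (adjusted p = 0.105) or non-target array 2 (0.0924). Immune cell markers had 0 of 19 called by limma, over all genes and adjusted over the list alone, with 2 higher and 0 lower at an unadjusted p under 0.05.

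With siKLF9 alone, the list with the smallest camera p was that of the interferon-response genes, the transcripts that type I interferon induces. Of 42 members, 10 fell and 0 rose (unadjusted 0), and adjusted over the list alone 26 fell and 0 rose (camera adjusted p = 6e-25; adjusted p = 0.109 with an estimated correlation). CMPK2, a mitochondrial nucleotide kinase, fell by 1.20 ± 0.12 (adjusted p = 0.023) and PARP12 by 0.82 ± 0.06 (adjusted p = 0.017). OAS2, which makes the activator of RNase L, fell by 0.77 ± 0.07 (adjusted p = 0.023) and IFIH1, the RNA sensor MDA5, by 0.56 ± 0.05 (adjusted p = 0.019). All 38 varying members were lower, with a median of -0.45. Outside this list, the rises included TMEFF2 (2.15 ± 0.24), LINC01279 (1.72 ± 0.16), the adenylate kinase AK5 (1.64 ± 0.09), the pentraxin PTX3 (1.60 ± 0.12) and the immediate early gene EGR1 (1.42 ± 0.17), with the secreted STC2 at 1.04. After KLF9 itself, falls were led by the endothelin receptor EDNRB (-1.61 ± 0.20) and CDK5R1, an activator of CDK5 (-1.41 ± 0.13). PLXDC2 fell by 1.15 ± 0.07, and the DNA repair gene NBN by 1.13 ± 0.06. The decidual markers PRL and IGFBP1 stood at -0.45 ± 0.28 (adjusted p = 0.81) and -0.95 ± 0.24 (adjusted p = 0.23).

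Across the genome, siKLF9 changed 134 genes, 54 higher and 80 lower, 21 of them at least 2-fold and 3 by under 0.2. Shifts were called for 8 of the 28 lists with the preset correlation and for 0 with an estimated one (unadjusted 7; fry 3). Besides the interferon list, the steroid-responsive genes had 0 of 18 higher (unadjusted 0) and 2 lower, KLF9 itself, a member of the list, and ERRFI1, a brake on EGF receptor signalling, at -0.59; adjusted over the list alone these were 0 and 3 (adjusted p = 0.109 with an estimated correlation). Of the 22 cAMP and CREB targets EGR1 rose, and SIK1 at -0.58 and PRKAR2B at -0.32 fell, or 1 and 4 adjusted over the list alone (adjusted p = 0.167 with an estimated correlation). Of 39 matrix proteases and inhibitors, ADAM19 at -1.31, MMP1 at -0.50 and PLAT at -0.30 fell and 0 rose (unadjusted 1), the same counts adjusted over the list alone (adjusted p = 0.164 with an estimated correlation). The DNA replication list rested on 1 call of 31, GINS1 at 1.07, with 2 higher and 0 lower adjusted over the list alone (adjusted p = 0.138 with an estimated correlation). The mitosis list had 0 calls of 35, with 0 adjusted over the list alone and 3 higher at an unadjusted p under 0.05 (adjusted p = 0.114 with an estimated correlation). Sterol synthesis had 0 of 19, with 2 higher adjusted over the list alone and 5 higher and 1 lower unadjusted (adjusted p = 0.138 with an estimated correlation). The pericyte list had 0 of 13, with 1 lower adjusted over the list alone and 2 lower unadjusted (adjusted p = 0.205 with an estimated correlation).

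The 134 calls became 304 without siKLF9 array 1 (225 higher and 79 lower) and 236 without siKLF9 array 2 (161 and 75), which turned the larger direction. They became 184 without non-target array 1 (37 higher and 147 lower), 57 without either array of both siRNAs, and 0 in limma on the compared groups alone (unadjusted 2098). The 8 lists became 4 without non-target array 1 and 5 without siKLF9 array 1. The calls of the interferon, steroid-responsive and DNA replication lists held without any 1 array. The other 5 were lost without some array, with adjusted p up to 0.354, 2 of them without siKLF9 array 2 and 2 without either siPGR array. Of the 27 calls named for siKLF9 in the text, 16 were lost by leaving out some array, with adjusted p up to 0.135, and 11 held throughout: LINC01279, AK5, PTX3, STC2, ADAM19, PLXDC2, NBN, PARP12, IFIH1, DENND6A and SLC40A1. Leaving out non-target array 1 or 2 lost 14 of them, either array of both siRNAs 12, either vehicle array 11, either siPGR array 4, siKLF9 array 1 lost 6 and siKLF9 array 2 lost 8.

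With siPGR, the interferon-response genes were shifted in the opposite direction to siKLF9. Of 42 members, 16 rose and 1 fell, and 31 and 1 adjusted over the list alone (camera adjusted p = 2.97e-22; adjusted p = 0.0767 with an estimated correlation). RSAD2, the antiviral enzyme viperin, rose by 3.13 ± 0.19 (adjusted p = 0.002), CMPK2 by 1.67 ± 0.12 (adjusted p = 0.0028), HERC5, the ligase that attaches ISG15, by 1.60 ± 0.11 (adjusted p = 0.0028) and IFIH1 by 0.92 ± 0.05 (adjusted p = 0.0013). The 1 member that fell was GBP1, at -0.55 ± 0.09 (adjusted p = 0.024), named after its value was seen. Among the other large rises were the activin subunit INHBE (4.21 ± 0.27), ENC1 (2.97 ± 0.44), CNIH3 (2.84 ± 0.24), PAG1 (2.51 ± 0.26), the phosphodiesterase PDE3B (2.29 ± 0.12) and EGR1 (2.19 ± 0.17). The decidual transcripts CNR1 (-3.13 ± 0.13), WNT4, a WNT ligand needed for decidualisation (-2.52 ± 0.41), RORB (-2.44 ± 0.15), RASD1 (-2.22 ± 0.17) and ALDH1A3 (-2.09 ± 0.14) fell, as did the matrix protein THBS1 (-2.21 ± 0.10). PRL at -0.93 ± 0.28 (adjusted p = 0.17) and IGFBP1 at -0.35 ± 0.24 (adjusted p = 0.71) did not pass the test.

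Decidual markers had 2 of 22 higher and 7 lower with siPGR, or 4 and 8 adjusted over the list alone (camera adjusted p = 0.00021; adjusted p = 0.0767 with an estimated correlation), among them DKK1 at -1.18 and LAMB1 at -1.07. The steroid-responsive genes had 0 higher (unadjusted 3) and 7 of 18 lower, or 2 and 8 adjusted over the list alone (4.96e-05; adjusted p = 0.0767 with an estimated correlation). Among them were GADD45B at -0.84, TSC22D3, the leucine zipper GILZ, at -0.63, ERRFI1 at -0.84 and HSD11B1 at -0.57. Of the contractile genes, 8 of 25 were lower and 0 higher (unadjusted 0), or 11 and 0 adjusted over the list alone (3.89e-08; adjusted p = 0.077 with an estimated correlation), led by the matricellular CCN1 at -1.08. Collagens and matrix genes had 1 of 45 higher and 4 lower, or 3 and 13 adjusted over the list alone (3.4e-06; adjusted p = 0.215 with an estimated correlation). Hypoxia and glycolysis genes had 5 of 30 higher and 3 lower, or 11 and 3 adjusted over the list alone (0.00029; adjusted p = 0.0767 with an estimated correlation), with the angiogenic factor VEGFA at 0.97, PDK4 at -0.91 and the glucose transporter SLC2A3 at -0.94. These calls and that of the interferon list held without any 1 array. On the same arrays, the ACTB control probe sets for both ends of the actin transcript fell. The 3′ one read 0.119 and 0.062 with the non-target siRNA and -0.277 and -0.344 with siPGR. The 5′ one read 0.289 and 0.166, and -0.712 and -0.768. Their 5′ minus 3′ difference was 0.14 with the non-target siRNA and -0.43 with siPGR, while that of GAPDH stayed between -0.07 and 0.14 on all 10 arrays. Each control probe set is centred on its own median, so such a difference is no absolute gap between the ends.

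Another 7 lists shifted with siPGR and lost their call without some array, with adjusted p up to 0.196: 2 without non-target array 1, 3 without non-target array 2, 4 without either siPGR array and 1 without either vehicle array. The IGF axis had 0 higher (unadjusted 2) and 3 of 17 lower, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.000787; adjusted p = 0.215 with an estimated correlation), with IGF1 at -1.93 and PAPPA at -1.43. The p53 and apoptosis genes had 3 of 26 higher and 2 lower, or 6 and 4 adjusted over the list alone (0.004; adjusted p = 0.215 with an estimated correlation). Matrix proteases had 0 higher (unadjusted 2) and 3 of 39 lower, or 0 and 4 adjusted over the list alone (0.00794; adjusted p = 0.0982 with an estimated correlation), MMP1 at -0.58 among them. The unfolded protein response had 4 of 27 higher and 1 lower, or 9 and 3 adjusted over the list alone (0.0259; adjusted p = 0.215 with an estimated correlation), with the stress transcription factors ATF4 at 0.74 and DDIT3 at 1.18. Histone and chromatin genes had 2 of 26 higher and 1 lower, or 3 and 1 adjusted over the list alone (0.0292; adjusted p = 0.147 with an estimated correlation), with HMGA2 at 1.38. Cytokines had 4 of 41 higher and 1 lower, or 6 and 1 adjusted over the list alone (0.0331; adjusted p = 0.205 with an estimated correlation), with the chemokine CXCL12 at 1.12. DNA replication genes had 0 calls of 31, over all genes and adjusted over the list alone, and 6 higher and 0 lower unadjusted (0.0409; adjusted p = 0.215 with an estimated correlation).

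Over all genes, siPGR changed 942, with 527 higher and 415 lower, 145 at least 2-fold and 47 by under 0.2, and 13 lists shifted, 0 with an estimated correlation (unadjusted 7; fry 15). The 942 calls became 586 without non-target array 1 (237 higher and 349 lower) and 568 without non-target array 2 (253 and 315), which turned the larger direction. Of the 42 calls named for siPGR in the text, those of ENC1, WNT4, FABP5, CDK5R1, SLC40A1 and GBP1 were lost by leaving out some array, with adjusted p up to 0.112. Of these 6, 4 were lost without non-target array 1, 5 without non-target array 2, 4 without siPGR array 1, 3 without siPGR array 2, 2 without either siKLF9 array and 1 without either vehicle array.

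With both siRNAs, 23 of the 42 interferon-response genes were higher and 1 lower, or 29 and 2 adjusted over the list alone (camera adjusted p = 1.67e-16; adjusted p = 0.0702 with an estimated correlation). RSAD2 rose by 3.84 ± 0.19 (adjusted p = 0.00048), CMPK2 by 1.96 ± 0.12, HERC5 by 1.95 ± 0.11 and IFIH1 by 1.05 ± 0.05, and GBP1 fell by 1.06 ± 0.09. Of the 38 varying members, 36 had a value above 0, the exceptions being GBP1 and PARP12 at -0.21 (adjusted p = 0.11), the latter named after its value was seen. Outside the list, large rises included ENC1 (4.21 ± 0.44), INHBE (3.71 ± 0.27), CNIH3 (3.54 ± 0.24), EGR1 (3.36 ± 0.17), the hyaluronan-binding CEMIP (3.13 ± 0.23) and TNFSF13B, the B-cell factor BAFF (2.67 ± 0.19). The largest falls were WNT4 (-3.98 ± 0.41), the nuclear RNA MALAT1 (-3.44 ± 0.64), CNR1 (-3.43 ± 0.13), ADAMTS3 (-3.38 ± 0.26), IGF1 (-3.02 ± 0.10), APCDD1 (-2.97 ± 0.31), ALDH1A3 (-2.94 ± 0.14) and RORB (-2.76 ± 0.15). PRL fell by 1.46 ± 0.28 (adjusted p = 0.026), and IGFBP1 stood at -0.85 ± 0.24 (adjusted p = 0.1). IGFBP1 came under the threshold without vehicle array 1 or 2 (adjusted p = 0.0124) and without the flat genes (0.0346). It did so too with quantile normalization, at -1.27 (adjusted p = 0.00529). That step forces 1 distribution on arrays whose centred values spread unequally, so it alters the differences between arrays as well.

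**Figure D2:**
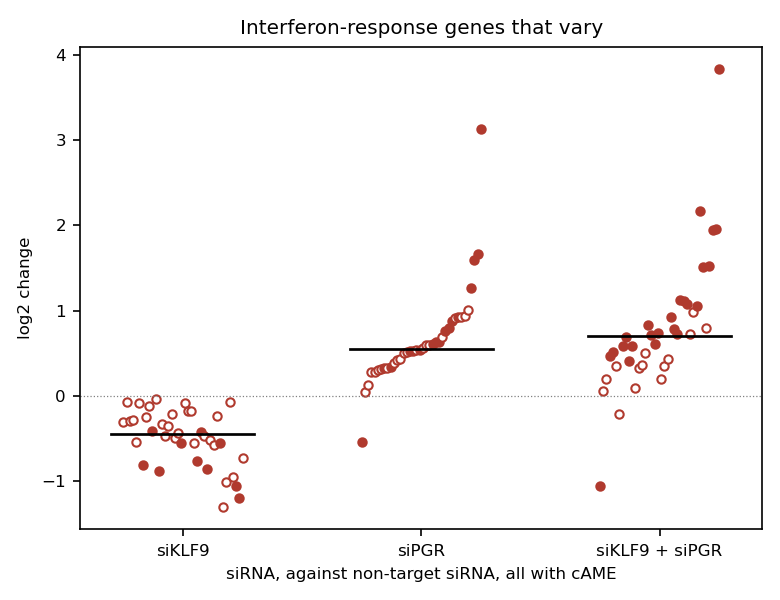
Log2 change of each of the 38 varying interferon-response genes (points; filled where called at an adjusted p below 0.05, open otherwise) with siKLF9, siPGR or both against the non-target siRNA, all with cAME, 2 arrays per group; the vertical axis is log2 change, bars are medians and the dotted line is 0. All 38 lay below 0 with siKLF9, 37 above 0 with siPGR and 36 above 0 with both, with medians of -0.45, 0.55 and 0.70.

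Collagens and matrix genes had 1 of 45 higher and 18 lower with both siRNAs, or 3 and 27 adjusted over the list alone (camera adjusted p = 2.26e-10; adjusted p = 0.129 with an estimated correlation). THBS1 stood at -2.20, LAMB1 at -1.40, TNC at -1.15 and the basement membrane protein NID2 at -0.88. Contractile genes had 0 higher (unadjusted 0) and 10 of 25 lower, or 0 and 12 adjusted over the list alone (7.71e-09; adjusted p = 0.0679 with an estimated correlation). LMOD1 stood at -2.56, smooth muscle actin ACTA2 at -1.19 and CCN1 at -1.12. The 5′ minus 3′ difference of the ACTB control probe sets was -0.59 on these arrays, against 0.14 with the non-target siRNA. Hypoxia and glycolysis genes had 15 of 30 higher and 2 lower, or 19 and 4 adjusted over the list alone (6.49e-08; adjusted p = 0.051 with an estimated correlation). Hexokinase HK2 stood at 1.79, VEGFA at 1.20, pyruvate kinase PKM at 0.69 and PDK4 at -1.24. Decidual markers had 3 of 22 higher and 8 lower, or 4 and 13 adjusted over the list alone (2.86e-05; adjusted p = 0.051 with an estimated correlation). Steroid-responsive genes had 2 of 18 higher and 9 lower, KLF9 among them, or 4 and 9 adjusted over the list alone (7.48e-05; adjusted p = 0.0559 with an estimated correlation), with TSC22D3 at -0.94 and ERRFI1 at -1.34. The IGF axis had 1 of 17 higher and 8 lower, or 1 and 10 adjusted over the list alone (7.48e-05; adjusted p = 0.129 with an estimated correlation), with PAPPA at -1.58 and the receptor substrate IRS2 at -0.59. Matrix proteases had 3 of 39 higher and 12 lower, or 3 and 15 adjusted over the list alone (7.48e-05; adjusted p = 0.051 with an estimated correlation), with the collagenase MMP1 at -1.44 and ADAMTS5 at -1.23. Sterol synthesis had 4 of 19 higher and 0 lower (unadjusted 0), or 5 and 0 adjusted over the list alone (0.00256; adjusted p = 0.07 with an estimated correlation), with DHCR7 at 0.95. Cytokines had 7 of 41 higher and 1 lower, or 8 and 2 adjusted over the list alone (0.00641; adjusted p = 0.105 with an estimated correlation), with IL1B at 1.32, CXCL12 at 1.12 and the hyaluronan-modifying TNFAIP6 at 1.06.

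The remaining list calls with both siRNAs each depended on single arrays. Oxidative defence had 9 of 27 higher and 2 lower, or 12 and 6 adjusted over the list alone (camera adjusted p = 0.00477; adjusted p = 0.129 with an estimated correlation), and its call was lost without array 2 of both siRNAs (adjusted p = 0.0514). Retinoid and steroid metabolism had 2 of 31 higher and 9 lower, or 3 and 9 adjusted over the list alone (0.0246; adjusted p = 0.105 with an estimated correlation), lost without the same array (adjusted p = 0.0726). The pericyte list had 0 higher (unadjusted 1) and 1 of 13 lower, ACTA2, or 1 and 3 adjusted over the list alone (0.0246; adjusted p = 0.129 with an estimated correlation), lost without array 1 of both siRNAs (adjusted p = 0.13). Of the cAMP and CREB targets 9 of 22 were higher and 3 lower, or 9 and 4 adjusted over the list alone (0.0282; adjusted p = 0.175 with an estimated correlation). That call was lost without vehicle array 1 or 2 (adjusted p = 0.1), non-target array 1 (0.0502), or array 1 (0.0641) or 2 (0.0687) of both siRNAs. The pair changed 2023 genes, 1107 higher and 916 lower, 347 at least 2-fold (144 higher and 203 lower) and 75 by under 0.2, and 14 lists shifted, 0 with an estimated correlation (unadjusted 10; fry 20). Without non-target array 1, the genes were 679 higher and 684 lower, and an unadjusted p under 0.05 with at least 1.5-fold gave 540 and 705. Among the 50 genes called and named for the pair, 48 calls held without any 1 array. That of PRL was lost without non-target array 1 (adjusted p = 0.123) or 2 (0.0593), siPGR array 1 or 2 (0.0552), or array 1 of both siRNAs (0.0753). That of MALAT1 was lost without non-target array 1 (adjusted p = 0.0963), siPGR array 1 or 2 (0.0503), or array 1 (0.103) or 2 (0.0814) of both siRNAs.

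**Figure D3:**
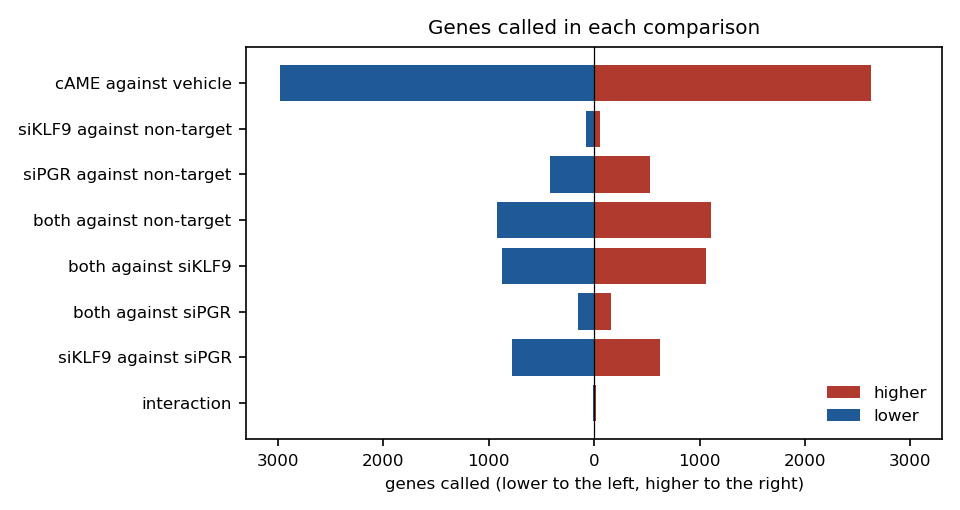
Number of genes called at an adjusted p below 0.05 in each comparison (horizontal axis, lower to the left and higher to the right), from 2 arrays per group. cAME against vehicle called 5611 genes, siKLF9 134, siPGR 942, both 2023 and the interaction 27.

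The pair was also set against each single siRNA. Against siKLF9 alone, the pair raised PLSCR1, a phospholipid scramblase induced by interferon, by 1.47 ± 0.03, IFIH1 by 1.62 ± 0.05 and the decoy receptor TNFRSF11B by 2.91 ± 0.10, while CHST7 stood at -1.42, TGFBR3 at -1.46 and PAPPA at -1.45. PGR fell by 2.90 ± 0.21. The second KLF9 probe set was lower with the pair than with siKLF9 alone, at -0.60 ± 0.09 (adjusted p = 0.0144 over all tested probe sets). The 3 others gave -0.003, 0 and -0.047. For the main KLF9 probe set the difference was -0.94 ± 0.19 (adjusted p = 0.035). The call was lost without vehicle array 1 or 2 (adjusted p = 0.0575), non-target array 1 or 2 (0.0649), siKLF9 array 1 (0.1) or 2 (0.156), or array 2 of both siRNAs (0.115). That comparison called 1936 genes, 1063 higher and 873 lower, 359 of them at least 2-fold and 90 by under 0.2. Without siKLF9 array 1 these were 670 higher and 799 lower, and an unadjusted p under 0.05 with at least 1.5-fold gave 527 and 715. Against siPGR alone, the pair raised TNFAIP6 by 0.95 ± 0.03, G0S2, an inhibitor of fat breakdown, by 1.39 ± 0.06 and FJX1 by 1.34 ± 0.06. QDPR, at -1.42 ± 0.05, ACTR8, at -2.24 ± 0.08, and the iron exporter SLC40A1, at -0.82 ± 0.03, were lower. KLF9 stood at -2.52 ± 0.19 (adjusted p = 0.0085) and PGR at -0.10 ± 0.21 (adjusted p = 1). Here 316 genes were called, 163 higher and 153 lower, 44 at least 2-fold and 17 by under 0.2. The 316 calls became 159 without non-target array 1 or 2 (72 higher and 87 lower), 200 without siKLF9 array 1 or 2 (91 and 109), and 0 in limma on the 2 groups alone (unadjusted 2139). Single arrays moved the split, to 119 higher and 281 lower without siPGR array 1, 95 and 209 without siPGR array 2, and 216 and 94 without array 1 of both siRNAs. The single siRNAs differed from each other in 1401 genes, 623 higher and 778 lower with siKLF9, 244 at least 2-fold and 59 by under 0.2. Without siKLF9 array 1 these were 633 and 462. Of the 42 interferon-response genes, 27 were lower with siKLF9 than with siPGR and 0 higher, with a median difference of -0.97.

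The interaction asks whether the joint change departed from the sum of the single changes, and it passed for 27 genes, 18 higher and 9 lower than the sum, 8 of them at least 2-fold and 0 by under 0.2. TNFAIP6 stood 1.03 ± 0.04 above the sum (adjusted p = 0.0088), PLSCR1 0.81 ± 0.04 (adjusted p = 0.011), VWA5A 1.60 ± 0.11 (adjusted p = 0.021), the ERK phosphatase DUSP6 1.87 ± 0.14 (adjusted p = 0.026) and TMEM158 0.82 ± 0.06 (adjusted p = 0.026). Below the sum lay CNTN4 at -0.28 ± 0.02, ACTR8 at -1.82 ± 0.12, H2AC17 at -0.69 ± 0.05, JAZF1 at -0.54 ± 0.04 and HAP1 at -0.29 ± 0.02, with adjusted p from 0.021 to 0.026. The interferon list lay above the sum, with IFIH1 at 0.69 ± 0.06 as its 1 call among 42, or 23 adjusted over the list alone, and 0 below (unadjusted 0), with a camera adjusted p = 4.88e-21 (adjusted p = 0.148 with an estimated correlation). Hypoxia and glycolysis genes had 0 of 30 called over all genes, 14 above and 1 below the sum unadjusted, and 12 above and 1 below adjusted over the list alone (4.15e-08; adjusted p = 0.0583 with an estimated correlation). Of cAMP and CREB targets 0 of 22 were called, with 8 above the sum adjusted over the list alone and also unadjusted (8.86e-05; adjusted p = 0.148 with an estimated correlation). Collagens lay below the sum (median -0.224), with 0 of 45 called (unadjusted 2 above and 8 below), or 1 below adjusted over the list alone. Their camera adjusted p was 5.41e-07, or 0.232 with an estimated correlation. The unfolded protein response lay below (median -0.11), with 0 of 27 called and 1 below adjusted over the list alone (camera 0.00103, or 0.167). The IGF axis and the DNA replication, contractile, retinoid, histone and mesenchymal lists also lay below, and oxidative defence above. With trend and robust variance estimates limma called 0 genes for the interaction (unadjusted 1278). In all 12 lists shifted, 0 with an estimated correlation (unadjusted 8; fry 7), and 5 of the 12 held without any 1 array: interferon, hypoxia, cAMP, collagens and the unfolded protein response.

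Single arrays decided much of the interaction. The 27 calls became 12 without vehicle array 1 or 2, 103 and 83 without non-target array 1 and 2, and 180 and 132 without siKLF9 array 1 and 2. They became 194 and 97 without siPGR array 1 and 2, and 123 and 180 without array 1 and 2 of both siRNAs. The larger direction turned without siKLF9 array 1 (44 above and 136 below the sum) or 2 (34 and 98) and without siPGR array 1 (49 and 145) or 2 (31 and 66). Among the 11 named calls, those of TMEM158, ACTR8, JAZF1, HAP1 and IFIH1 were lost without vehicle array 1 or 2. That of HAP1 was lost also without non-target array 2, and that of IFIH1 without siKLF9 array 2, siPGR array 2 or array 1 of both siRNAs, with adjusted p up to 0.06. For the lists, 7 of 12 calls were lost without some array, with adjusted p up to 0.238. The numbers lost were 4 each without non-target array 2, siKLF9 array 1, siPGR array 2 and array 1 of both siRNAs, 3 without siKLF9 array 2, 2 without array 2 of both, and 1 each without non-target array 1 and siPGR array 1.

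Genes called in the same direction with each single siRNA and with the pair numbered 28, with 12 higher and 16 lower. EGR1 rose by 1.42, 2.19 and 3.36 with siKLF9, siPGR and the pair, ZFP69B by 1.47, 1.67 and 1.95, AK5 by 1.64, 1.05 and 1.93, and the fatty acid carrier FABP5 by 0.93, 0.94 and 1.56. Among those that fell, CDK5R1 gave -1.41, -1.04 and -1.57, the caveolin CAV2 -0.81, -0.79 and -1.83, DENND6A -0.96, -0.79 and -1.62, ERRFI1 -0.59, -0.84 and -1.34, MMP1 -0.50, -0.58 and -1.44, and SLC40A1 -0.73, -0.25 and -1.07. Independent lists of these sizes, drawn from all 19740 genes, would share 0.0808 higher and 0.078 lower genes. These numbers are a low yardstick, since the 7467 flat genes gave only 0, 5 and 6 calls with siKLF9, siPGR and the pair. A gene's spread also enters every comparison alike, so genes of small spread tend to be called together in either direction. The single siRNAs shared 12 higher and 17 lower genes, against 1.44 and 1.68 for independent lists, and moved 27 genes in opposite directions, 8 of them higher with siKLF9 and 19 lower, against 1.14 and 2.14. With the pair, siKLF9 shared 20 higher and 47 lower genes, against 3.03 and 3.71, and siPGR 439 and 352, against 29.6 and 19.3. The 28 genes became 128 and 109 without non-target array 1 and 2, and 13 and 12 without array 1 and 2 of both siRNAs, and the 29 shared by the single siRNAs became 131 and 110, and 13 and 13.

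The comparisons share their non-target arrays, and these cannot be split into parts of 2, so part of any excess in the same direction may come from them. Over the 12273 varying genes, the siKLF9 and siPGR changes had a covariance of 0.00758, against 0.0131 simulated from the shared arrays alone, and a correlation of 0.10, against 0.50 simulated. For siKLF9 and the pair the covariance was 0.0233 against 0.0131 and the correlation 0.24 against 0.50. For siPGR and the pair the covariance was 0.105 against 0.0131 and the correlation 0.79 against 0.50. Observed minus simulated covariance was thus -0.00555 for the single siRNAs, 0.0102 for siKLF9 and the pair, and 0.092 for siPGR and the pair. With 1 non-target array per comparison, the covariances were -0.00355, 0.0121 and 0.094. The simulated correlation of 0.50 follows from the shared group of arrays by itself, in draws that hold no real change. The observed correlations hold real changes, so only the covariances can be set against each other. Genes are not independent replicates of each other.

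The last comparison asked how far each knockdown moved cAME-responsive genes back towards vehicle. Of the genes that siKLF9 changed, 101 (75.4%) had also changed with cAME, and 68 of these (67.3%) moved back, among them CDK5R1 and ERRFI1, which cAME had raised by 1.72 and 1.28, and EGR1 and AK5, at -3.01 and -4.45 with cAME. KLF9 itself is counted in each of these sets where its siRNA was present. With siPGR, 716 (76%) had changed with cAME and 465 (64.9%) moved back, among them CNR1, RORB and ALDH1A3. With the pair, 1402 (69.3%) had changed with cAME and 824 (58.8%) moved back, among them WNT4, IGF1 and APCDD1. Of the genes that moved back, cAME had raised 39 and lowered 29 for siKLF9, against 10.7 and 8.16 for independent lists, 220 and 245 for siPGR, against 55.2 and 79.6, and 382 and 442 for the pair, against 122 and 167. Genes that moved further in the direction of cAME, raised and lowered, were 6 and 27 for siKLF9, against 7.19 and 12.1, 156 and 95 for siPGR, against 70.2 and 62.7, and 346 and 232 for the pair, against 147 and 138. The numbers for independent lists carry the limit given above for flat genes and shared spread. The non-target arrays enter both sides with opposite signs. Covariances with the cAME change were -0.0389 for siKLF9, -0.0684 for siPGR and -0.0785 for the pair, against simulated values of -0.0132, -0.0132 and -0.0131. Correlations were -0.19, -0.24 and -0.22. The simulated -0.50 is again set by the shared group alone and cannot be compared with them. With the pair, IGF1 was still 5.70 and ALDH1A3 1.84 above vehicle, and CNR1 was 4.78 above it with siPGR. RSAD2 passed the vehicle level, by 0.75 (adjusted p = 0.033) with siPGR and 1.46 (adjusted p = 0.0021) with the pair. The interferon list as a whole came back only to about the vehicle level. The median centred value of its 38 varying members was 0.148 and 0.249 on the vehicle arrays and -0.451 and -0.338 on the cAME non-target arrays. It was 0.058 and 0.149 with siPGR, 0.29 and 0.206 with the pair, and -0.822 and -0.791 with siKLF9. The 68 genes of siKLF9 became 147 and 133 without non-target array 1 and 2 and 31 without either array of both siRNAs, and the 465 of siPGR became 289 without siPGR array 2.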

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

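The tests of the patterns weighed here were chosen after the result was seen, other than that of a single array deciding the interferon pattern and that of the number of genes called in additive simulated arrays. Genes and lists were picked out because the joint change differed from the sum of the single changes by the interaction test, and the unnamed probe sets and the actin controls because they carry signal outside the reported comparisons.

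The interferon-response genes were lower with siKLF9 and higher with siPGR and with both than with the non-target siRNA. This is 1 of 12 lists shifted in the interaction. With cAME against vehicle, 29 of 42 members had fallen. By the array medians given above, the list lay near the vehicle level with siPGR and with both. A single array deciding is argued against by the smallest ratio of a list median without 1 array to the full median, 0.815 over the 3 comparisons. A response alike for every siRNA, whatever its sequence, would cancel, since every array carried an siRNA and the non-target siRNA is the control. The siKLF9 median of -0.453, with 38 of 38 varying members lower, and the 37 members higher with siPGR argue against such an equal response. These values are part of the pattern itself and so no separate test. A response that differs in strength between the siRNAs stays open. Immune cells among the stromal cells stay open: their 19 markers had a median change with siPGR of -0.005, against 0.54 for the list, but 11 of the 19 were flat, 7 of the 8 others (median -0.006, highest 0.321) varied on 1 array alone, and no level shows whether these could have moved. Sequence-specific effects of the siRNAs stay open too, since the titles give 1 siRNA name per target, no sequence and no meaning of pool. Opposed effects of KLF9 and PGR on interferon signalling were not tested apart from the siRNAs. If these only added up, the pair would lie at the sum of the single changes. The varying members lay above that sum by a median of 0.503. Adjusted over the list alone, 23 of 42 members lay above and 0 below. These values argue against opposed effects that only add up, for the rise with the pair. Each of these explanations may still account for a part of the pattern. The list's calls do not hold with an estimated correlation.

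More genes were called with both siRNAs (2023) than with siKLF9 (134) or siPGR (942). The pair and siKLF9 differed in 730 genes in the fit on those 2 groups alone, which holds no non-target array. That difference does not come from the non-target arrays, but it does not show which group lay further from them. The calls do not settle the chance values of the shared non-target arrays. The pair against siPGR alone called 159 genes in a fit without those arrays. In limma on the 2 groups alone, with 2 residual degrees of freedom, it called 0 (unadjusted 2139). A ratio of calls against each non-target array alone, tried after that result, decides nothing, since the array is still shared. With the noise of each comparison taken off, the variance over the 12273 varying genes was 0.148 for the pair, 0.076 for siPGR and 0.0285 for siKLF9. That argues against equal added noise as the source of the larger spread with the pair. The noise was drawn for each gene independently, so chance values shared by many genes stay open. For the sum of the single changes, the test written first counted the genes called in additive simulated arrays, and gave a median of 3853 (3709 to 3982), above the observed count in 100 of 100 draws, which taken alone would fit a sum; the same kind of simulation fed the joint changes themselves, shrunk, gave a median of 3016.5 (2946 to 3138) against 2023 observed, so it overshoots and decides nothing, while the summed changes, shrunk, gave 2153 (2099 to 2292). After that result was seen, the noise-corrected variance was compared instead, with the opposite outcome. The sum carried 62.9% of the variance of the joint change, 60.9 to 65.4 over 100 draws of the noise. With the noise of the residuals it carried 55.7%, so the sum may not account for the whole spread of the joint change. The additive draws gave at most 2 interaction calls against 27. That adds nothing to the interaction test itself, whose adjustment keeps calls few where no interaction is put in. The observed interaction calls became 0 with trend and robust variance estimates (unadjusted 1278). With the noise taken off, the interaction had 25.3% of the variance of the joint change, or 20% with the noise of the residuals. KLF9 was lower with the pair than with siKLF9 alone (-0.94), so deeper loss of KLF9 and a true interaction of the 2 factors cannot be told apart here, because the groups differ in PGR as well.

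Other results stood out by the interaction test or outside the comparisons. Of 27 genes with an interaction, TNFAIP6 (1.03), PLSCR1 (0.81), VWA5A (1.60), DUSP6 (1.87) and TMEM158 (0.82) lay above the sum of the single changes. Below the sum lay CNTN4 (-0.28), ACTR8 (-1.82), H2AC17 (-0.69), JAZF1 (-0.54) and HAP1 (-0.29). Among 13486 probe sets without a single gene name, 227 changed at least 2-fold with cAME, 2 with siKLF9, 25 with siPGR and 47 with both. The 5′ minus 3′ difference of the ACTB control probe sets was lower with both siRNAs than with the non-target siRNA, by -0.728, while that of GAPDH differed by 0.052. Both ACTB ends were lower with both siRNAs, the 5′ one at -0.931 and -0.841 and the 3′ one at -0.336 and -0.253.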

How the results depend on the processing

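Leaving out the flat genes was added after the data were seen, as was a fit of both against siPGR without the non-target cAME arrays (159 genes, 139 of them among the 316); the other alternatives printed here were planned. A filter on probe sets at level 6 or above was not run, because the values are centred and carry no level, and no filter at all was the setting used. Where an alternative moved a count by more than 1.5 times, the cause was not tested unless stated.

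Of 207 values of named genes, 115 kept their direction and their side of the threshold under all 18 alternatives, 31 lost their call by leaving out 1 array, and 0 changed sign as a call. The fit on the compared groups alone lost 82, and it has fewer arrays to estimate the spread. Equal array medians lost 1 and moved no count by more than 1.5 times, nor did leaving out the flat genes. No scaling moved the share of higher calls by over 10 points or the median of all genes by over 0.1. Other settings did turn the larger direction: an unadjusted p under 0.05 with at least 1.5-fold gave 540 higher and 705 lower for both, 527 and 715 for both against siKLF9 and 171 and 212 for the interaction. For both against siPGR it gave 127 and 238, every probe set 226 and 252, the mean of a gene's probe sets 214 and 223, trend and robust estimates 66 and 79, at least 2-fold 15 and 29, and leaving out the flat genes 99 and 162.

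With every probe set on its own, which tests more features, the calls became 12946 for cAME, 1533 for siPGR, 3417 for both, 3318 for both against siKLF9, 478 for both against siPGR, 2434 for siKLF9 against siPGR and 52 for the interaction, and 796 and 1453 cAME-responsive features moved back with siPGR and with both. Quantile normalization gave 2532 for cAME, 339 for siKLF9, 1479 for siPGR and 65 for the interaction, 110 genes shared by the single siRNAs, 106 by all 3 comparisons, 197 and 723 moved back with siKLF9 and siPGR, and 5 lists in the interaction. The mean of a gene's probe sets gave 56 for the interaction and 107 moved back with siKLF9.

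The fit on the compared groups alone gave 3659 for cAME, 0 for siKLF9 (2098 at an unadjusted p under 0.05), 183 for siPGR, 842 for both, 730 for both against siKLF9, 0 for both against siPGR (unadjusted 2139), 458 for siKLF9 against siPGR and 12 for the interaction. Trend and robust variance estimates gave 52 for siKLF9, 145 for both against siPGR, 0 for the interaction (unadjusted 1278), 8 genes shared by the single siRNAs, 8 by all 3 comparisons and 24 moved back with siKLF9.

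An unadjusted p under 0.05 with at least 1.5-fold gave 3395 for cAME, 273 for siKLF9, 1245 for both, 1242 for both against siKLF9, 383 for the interaction, 47 shared by the single siRNAs, and 120, 309 and 444 moved back with siKLF9, siPGR and both. The adjusted threshold with at least 2-fold, stricter by construction, gave 1675 for cAME, 21 for siKLF9, 145 for siPGR, 347 for both, 359 for both against siKLF9, 44 for both against siPGR, 244 for siKLF9 against siPGR, 8 for the interaction, 4 shared by the single siRNAs, 4 by all 3 comparisons, and 10, 80 and 146 moved back.

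Arrays with the same replicate number did not deviate together: the correlations of their deviations over 12273 genes ran from -0.2 to 0.11 between groups. With the replicate number as a block, siKLF9 called 13 genes, both against siPGR 161 (78 higher and 83 lower) and the interaction 5, with 3 genes shared by the single siRNAs, 3 by all 3 comparisons and 6 moved back with siKLF9, and KLF9 with siKLF9 stood at -1.82 (adjusted p = 0.0741).

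Camera with an estimated correlation called 5 lists for cAME and 0 for siKLF9, siPGR, both and the interaction (unadjusted 7, 7, 10 and 8), and fry called 26 for cAME, 3 for siKLF9 and 7 for the interaction. Without 1 array, counts ran from 57 to 304 for siKLF9, 568 to 821 for siPGR, 159 to 453 for both against siPGR and 12 to 194 for the interaction. The genes shared by the single siRNAs ran from 13 to 131, those shared by all 3 comparisons from 12 to 128, those moved back from 31 to 147 with siKLF9 and 289 to 410 with siPGR, and the lists for siKLF9 from 4 to 8. KLF9 with siKLF9 ran from -1.91 to -1.73 without 1 array, with an adjusted p up to 0.0828. With 2 arrays per group and no level for any probe set, signal over background could not be assessed.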

Other observations

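The test of the ERK-output genes in this part was chosen after 3 of its members had been noticed among the large changes, and its prediction was written before the remaining members were looked at.

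Genes induced by ERK signalling were not among the fixed lists. A hypothesis was that they rise as a set when PGR is lost, since EGR1 (2.19), DUSP4 (2.23) and DUSP6 drew attention. Without these 3 genes, the 17 other tested members of a list written for the purpose had a median change of -0.044 with siPGR (camera p = 0.701, and 0.752 with an estimated correlation). Of the 17, 3 were called higher and 2 lower, so a rise as a set was not borne out for siPGR. With both siRNAs the median of the 17 was 0.148, with 5 called higher and 1 lower (camera p = 0.0345, and 0.126 with an estimated correlation), which was not the prediction. All 20 members together gave p = 0.000229 with both siRNAs (0.0416 with an estimated correlation), a value that includes the 3 genes it was drawn from. With cAME against vehicle the list moved the other way, with 3 of 20 members higher, 11 lower and a median of -1.06.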
